A study of Homo sapiens with 6 samples.

How the data were processed

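Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed with an antibody against SOX2, an HMG-box transcription factor of pluripotent and neural progenitor cells, and with an antibody against RNA polymerase II (Pol II). The cells were H9, an established human embryonic stem cell line (hESC), and neural progenitor cells differentiated from H9 (hNPC). Per the labels' protocols, differentiation used Noggin, SB431542 and Compound C, after which neural rosettes were picked, dissociated and kept in medium with bFGF. The series holds 6 samples: 1 SOX2, 1 Pol II and 1 input library per cell type. Samples were grouped by their titles. The cell type tag reads hESC for the hNPC samples as well, whereas their titles and source names give hNPC. The 2 input libraries were not analysed here.

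Per the submitters' processing notes, hg19, Bowtie 0.12.7 and MACS2 2.0.10 were used. Settings, thresholds, duplicate handling and the choice of control are not given in the sources used here. Each of the 4 deposited files analysed is a peak list with 3 columns, the chromosome, start and end of each peak, for 1 library, so peaks were called per sample and not on pooled replicates. The values in these deposited files are positions only, with no score or read count, so the depth of each library is unknown. A longer list can reflect a deeper or better enriched library as well as more occupied sites. The narrowest SOX2 peaks measured 146 bp in both cell types and the narrowest Pol II peaks 199 bp in both. Starts were raised by 1 to give 1-based positions.

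Peaks on chromosomes 1 to 22 and X were used. In each list no peak overlapped another. A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and hESC only or hNPC only otherwise. Because 1 peak can overlap several, the number of shared peaks differs slightly by direction. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error over peaks only. Neighbouring peaks are not independent, and no interval includes biological or technical variation, because each condition had 1 library. For the same reason no test between cell types was made and no p-value is given. Chance overlap was measured by shifting the query list along each chromosome by a random distance with wrap-around, 1000 times for the main overlaps and 200 times elsewhere. The outermost peak ends over all 4 lists set each chromosome's extent. Local chance was measured by moving each peak by 5 to 200 kb to either side. Windows of 100 kb were laid on a fixed grid, and peaks counted by their centres.

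Before the data were examined, the overlap rule, the circular shifts, a reciprocal 50% overlap, centres within 500 bp, all sequences, uniform placement and local displacement had been fixed. Comparisons of gene lists, transcription start sites, sequence motifs and the locus of SOX2 itself had also been planned. They need an hg19 genome and annotation and were not analysed here, and no gene is named at any peak. The rule for named regions (the 5 strongest peaks of each class and the 5 genes with most SOX2 peaks) was to rank by the authors' score. After the data had been seen, peak width took the place of the score and 100 kb windows the place of genes. Width is an imperfect stand-in for strength. The split of peaks by width, the Pol II overlap of each SOX2 class, the 10 kb distance, the windows, the ratios by chromosome and the comparison of Pol II classes with SOX2 classes were likewise chosen after seeing the data. So were the settings that use width, random thinning of a list (100 draws), removal of empty stretches over 1 Mb, joined Pol II loci and other distances.

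Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The overlap step was tested on 4 simulated copies of the hESC SOX2 list (17991 peaks each) with known sharing with the hNPC list. The planted share was recovered with an error of at most 0.379 percentage points, and the list with no planted sharing gave 1.13-fold over its shifts. The 3 overlap rules gave 0 mismatches with direct enumeration over the 198 hESC SOX2 peaks of chromosome 21.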

Results

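SOX2 and Pol II occupancy were mapped by ChIP-seq in H9 hESCs and in hNPCs derived from them, with 1 library per antibody and cell type. On chromosomes 1 to 22 and X the deposited lists held 17991 SOX2 peaks in hESCs and 67020 in hNPCs. For Pol II they held 2491 peaks in hESCs and 9322 in hNPCs. SOX2 peaks had a median width of 220 bp in hESCs (interquartile range 176 to 281 bp) and 282 bp in hNPCs (203 to 421 bp). Pol II peaks had medians of 332 bp (245 to 450 bp) and 364 bp (253 to 518 bp). All positions are given in hg19. Library depth is unknown, there were no replicates, and all bracketed intervals are exact 95% binomial intervals that cover counting error only.

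The first comparison asked how SOX2 occupancy differed between the pluripotent and the neural progenitor state. About as many hESC SOX2 sites were shared with hNPCs as were not. Of the 17991 hESC peaks, 8905 overlapped an hNPC peak, or 49.5% (48.8 to 50.2%), and 9086 were hESC only. In the other direction 8768 of the 67020 hNPC peaks overlapped an hESC peak, or 13.1% (12.8 to 13.3%), which left 58252 hNPC-only peaks. The hNPC list was 3.73 times as long as the hESC list and covered 23.4 Mb against 4.36 Mb, or 5.36 times as much sequence. When the hESC list was shifted along the chromosomes, 1.35% of its peaks overlapped the hNPC list on average and 1.65% at most in 1000 shifts. The observed share was 36.7-fold over that mean, 22.8-fold when centres within 500 bp counted as shared and 87.6-fold with a reciprocal overlap of 50%. With that reciprocal overlap the shares were 31.6% of hESC and 8.48% of hNPC peaks. With the hNPC list reduced to the hESC length the hESC share was 13.3% when peaks were drawn at random and 21.8% when the widest were taken, and the share of the widest hNPC peaks was 20.9%. A random draw lowers the hESC share nearly in proportion to the list length by construction, so the 13.3% adds no evidence.

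**Figure D1:**
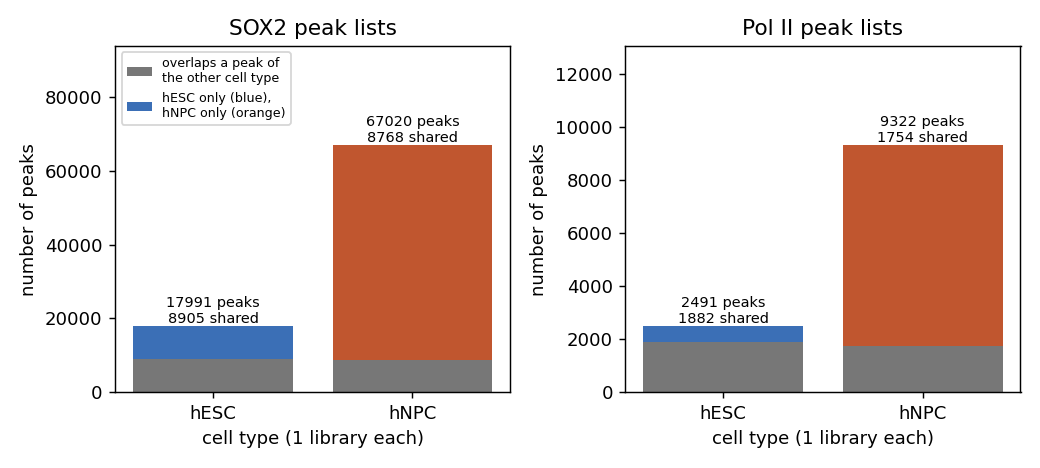
Number of peaks per list (y axes) for SOX2 and Pol II in hESCs and hNPCs, 1 library each, with peaks overlapping the other cell type in grey and the remainder in colour. The hNPC list is the longer one for both antibodies, and the grey part fills 49.5% of the hESC SOX2 bar and 75.6% of the hESC Pol II bar.

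Shared sites had wider peaks than sites of a single cell type. In hESCs the median width was 231 bp for shared and 210 bp for hESC-only peaks, and in hNPCs it was 364 bp for shared and 272 bp for hNPC-only peaks. Among the narrowest 10% of hESC SOX2 peaks 40.1% (37.8 to 42.4%) were shared, and among the widest 10% it was 63.7% (61.4 to 65.9%). For hNPC SOX2 peaks the shares ran from 5.66% (5.11 to 6.24%) in the narrowest to 26.6% (25.5 to 27.7%) in the widest 10%.

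**Figure D2:**
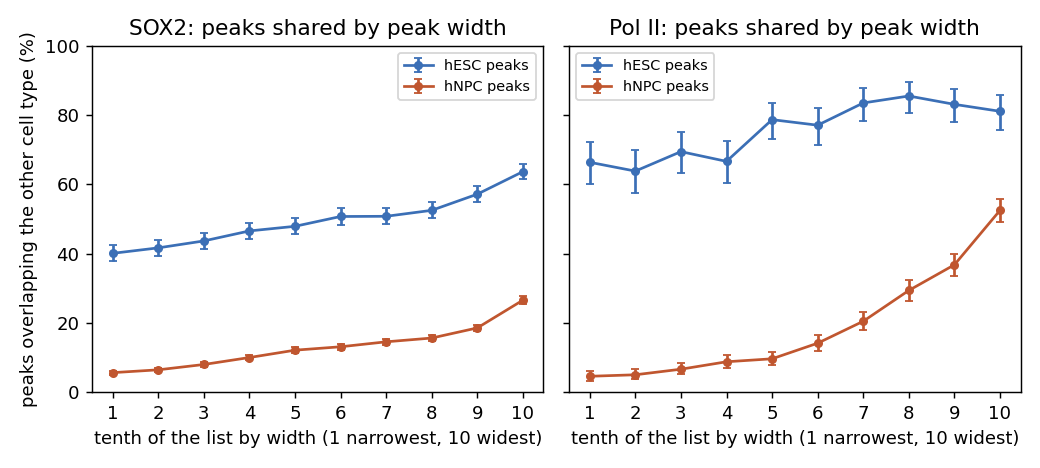
Percent of peaks overlapping a peak of the other cell type (y axis) in 10 bins of each list ordered by width (x axis, 1 narrowest), for SOX2 (left) and Pol II (right), with hESC lists in blue, hNPC lists in orange and exact 95% binomial intervals as bars. The widest bin reaches 63.7% for hESC SOX2 and 26.6% for hNPC SOX2 peaks, above the narrowest bin of each list.

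The widest hESC-only SOX2 peaks lay away from hNPC SOX2 peaks and from Pol II peaks. The widest measured 1006 bp, on chromosome 5 from 138903081 to 138904086. It was followed by peaks of 828 bp on chromosome 3 (106548788 to 106549615), 805 bp on chromosome X (37335697 to 37336501), 795 bp on chromosome 15 (96453820 to 96454614) and 785 bp on chromosome 2 (45017153 to 45017937). None of these 5 had an hNPC SOX2 peak or a Pol II peak of either cell type within 10 kb. Among all hESC-only SOX2 peaks 2.87% had an hESC and 5.11% an hNPC Pol II peak within 10 kb, against 1.38% and 4.43% on average for shifted lists. Having no listed Pol II peak nearby was therefore not particular to the widest peaks. The hESC Pol II list held only 2491 peaks, so absence from it does not show absence of Pol II. The widest shared hESC peaks were 945 bp on chromosome 9 (92292692 to 92293636) and 943 bp on chromosome 8 (38388176 to 38389118), where the hNPC peaks measured 1130 bp and 1159 bp. The next 3 were on chromosome 13 (107448639 to 107449571, 933 bp), chromosome 3 (147652150 to 147652984, 835 bp) and chromosome 11 (10373443 to 10374276, 834 bp), and none of the 5 had a Pol II peak within 10 kb.

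Of the 5 widest hNPC-only SOX2 peaks 4 overlapped hNPC Pol II peaks, as did 2 of the 5 widest shared hNPC SOX2 peaks, with a Pol II list 3.74 times as long as that of hESCs. Over the full classes 5.07% of hNPC-only and 11.4% of shared hNPC SOX2 peaks did so, in the opposite order. The 5 widest peaks therefore do not stand for their class. The widest hNPC-only peak, 2874 bp on chromosome 5 (124107149 to 124110022), had no Pol II peak within 10 kb. The other 4 each overlapped at least 1 hNPC Pol II peak and no hESC Pol II peak lay within 10 kb of them. They measured 2615 bp on chromosome 3 (147104419 to 147107033), 2423 bp on chromosome 2 (44932545 to 44934967), 2398 bp on chromosome 2 (212376227 to 212378624) and 2332 bp on chromosome 6 (99088369 to 99090700). Around the chromosome 3 peak there were 10 hNPC SOX2 and 10 hNPC Pol II peaks within 10 kb, against 4 hESC SOX2 peaks and 0 hESC Pol II peaks.

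The 5 densest 100 kb windows of SOX2 peaks mostly differed between the 2 cell types, but all held peaks of both. Lists of unequal length were ranked, so the different ranks do not show that peaks gathered at different places. The densest hESC window, chromosome 13 from 100300001 to 100400000, held 11 hESC and 21 hNPC peaks. The densest hNPC window lay on the same chromosome from 100600001 to 100700000, with 30 hNPC and 4 hESC SOX2 peaks and with 19 hNPC and 5 hESC Pol II peaks. One window ranked among the 5 densest in both cell types, chromosome 3 from 181400001 to 181500000, with 9 hESC and 26 hNPC SOX2 peaks. The other hESC windows of the 5 densest lay on chromosome 3 (32800001 to 32900000, 10 hESC and 9 hNPC peaks), chromosome 8 (38300001 to 38400000, 9 and 10) and chromosome 14 (57300001 to 57400000, 9 and 8). The remaining hNPC windows were on chromosome 2 (145200001 to 145300000), with 24 hNPC and 5 hESC peaks, and on chromosome 5 from 71400001 to 71500000, with 24 and 2, and from 92900001 to 93000000, with 23 and 1. A window on chromosome 2 from 105400001 to 105500000 held 19 hNPC SOX2 peaks and 12 hNPC Pol II peaks and none from hESCs.

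**Figure D3:**
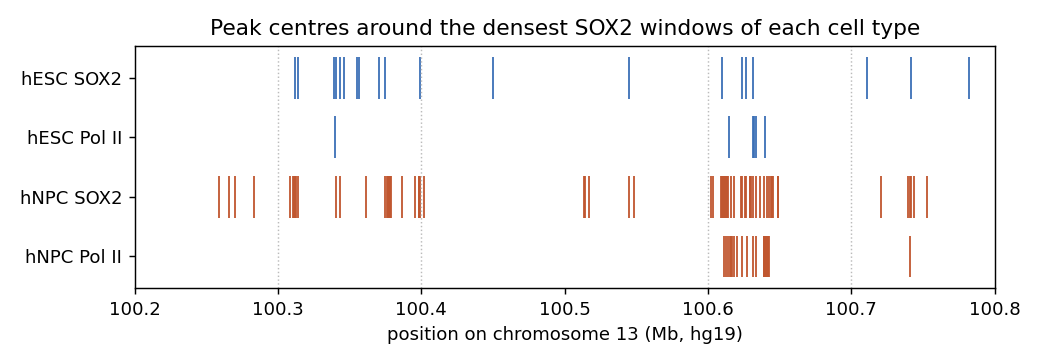
Positions of peak centres on chromosome 13 (x axis, Mb, hg19) in each of the 4 lists (rows), with hESC lists in blue, hNPC lists in orange and dotted lines marking the densest SOX2 window of each cell type. The window starting at 100.3 Mb holds 11 hESC and 21 hNPC SOX2 peaks, and the window starting at 100.6 Mb holds 4 and 30.

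Windows with more SOX2 peaks in hESCs existed despite the shorter list. Of the 22671 windows with a SOX2 peak, 18322 held more hNPC peaks, 2127 held more hESC peaks and 2222 held equal numbers. The largest hESC surplus was on chromosome 3 from 16700001 to 16800000, with 7 hESC and 0 hNPC peaks. On chromosome 6 from 42100001 to 42200000 there were 7 hESC peaks and 1 hNPC peak, and windows on chromosome 13 (28500001 to 28600000) and chromosome 15 (89500001 to 89600000) each held 5 and 0. In all, 61 windows held at least 3 hESC peaks and no hNPC peak, fewer than in any of 200 local displacements of the hESC list (100 to 156 windows). Displacement moves hESC peaks off the hNPC peaks that 49.5% of them overlapped, so this largely restates the sharing. No chance value was computed for the number of windows with more hESC peaks.

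The excess of hNPC SOX2 peaks was not the same on every chromosome. The ratio of hNPC to hESC peaks was 3.73 over all chromosomes used, 4.30 (3.92 to 4.72) on chromosome 13 and 4.20 (3.91 to 4.50) on chromosome 4. It was 2.79 (2.498 to 3.11) on chromosome 19 and 3.21 (2.89 to 3.58) on chromosome 20. The intervals of these chromosomes exclude the ratio of the whole list, as do those of chromosomes 1, 5, 16 and 17. No adjustment was made for the 23 chromosomes compared. Peaks were also taken as independent, although 59.5% of hNPC SOX2 peaks had another within 10 kb. The intervals are thus too narrow to settle whether chromosomes differ. Chromosome 19 held 2.48% of hESC and 1.86% of hNPC SOX2 peaks, against 7.03% of hESC and 6.39% of hNPC Pol II peaks.

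**Figure D4:**
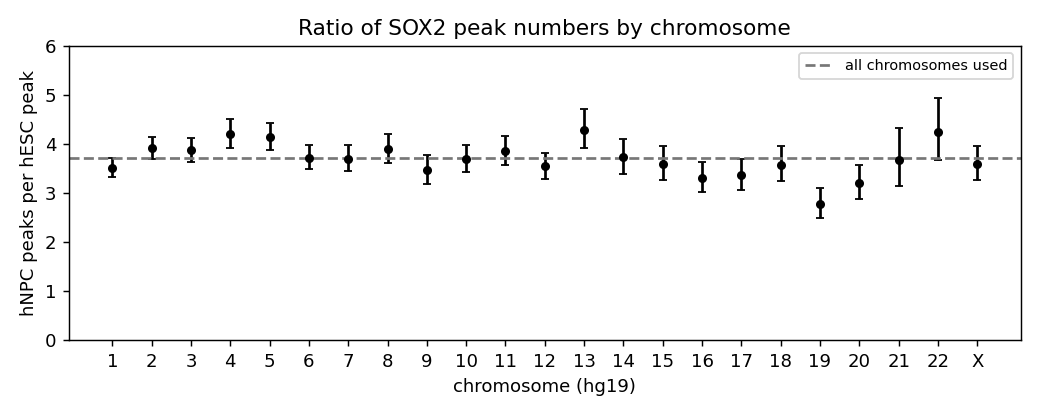
Number of hNPC SOX2 peaks per hESC SOX2 peak (y axis) on each chromosome (x axis), with exact 95% binomial intervals, and the ratio over all chromosomes used, 3.73, as a dashed line. Chromosome 19 has the lowest ratio, 2.79, and chromosome 13 the highest, 4.30.

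The second comparison followed Pol II, the enzyme that transcribes protein-coding genes, across the same change of state. Most hESC Pol II sites were also listed in hNPCs. Of 2491 hESC Pol II peaks 1882 overlapped an hNPC Pol II peak, or 75.6% (73.8 to 77.2%), and 609 were hESC only. Of 9322 hNPC Pol II peaks 1754 overlapped an hESC peak, or 18.8% (18.0 to 19.6%), and 7568 were hNPC only. Shifted hESC Pol II lists overlapped the hNPC list in 0.324% of peaks on average, so that the observed share was 233-fold over chance. Chance rose under local displacement, and the ratio was then 63.3-fold. The hNPC list was 3.74 times as long as the hESC list for Pol II and 3.73 times for SOX2. The shared percentage of hESC peaks was higher for Pol II than for SOX2, with intervals, for counting error only, that do not overlap. The Pol II lists were shorter and their peaks wider than those of SOX2. No setting matched the antibodies on list length or peak width, so these percentages are not directly comparable. With a reciprocal overlap of 50% the Pol II shares were 41.0% of hESC peaks, 514-fold over chance, and 10.95% of hNPC peaks. With each hNPC list reduced to the hESC length the hESC share was 20.6% for Pol II and 13.3% for SOX2 when drawn at random, and 47.5% and 21.8% when the widest peaks were taken. The values from random draws nearly follow from the list lengths by construction.

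The widest Pol II peaks of each list included some with and some without a Pol II peak of the other cell type. Each list was called separately at unknown depth, so peak widths do not show a difference in extent. The 5 widest hNPC peaks were on chromosome 3 (147126513 to 147137759, 11247 bp), chromosome 11 (65265023 to 65275610, 10588 bp), chromosome 6 (30576420 to 30585273, 8854 bp), chromosome 1 (156638729 to 156647483, 8755 bp) and chromosome 13 (95355878 to 95363631, 7754 bp). The peaks on chromosomes 3, 1 and 13 had no hESC Pol II peak within 10 kb and overlapped 4, 3 and 4 hNPC SOX2 peaks and 2, 1 and 2 hESC SOX2 peaks. The chromosome 11 peak overlapped 11 separate hESC Pol II peaks and the chromosome 6 peak overlapped 5. The widest hESC Pol II peak, 4388 bp on chromosome 1 (149856334 to 149860721), overlapped an hNPC peak of 4726 bp. Peaks of 3854 bp on chromosome 2 (67565951 to 67569804) and 3038 bp on chromosome 10 (53788035 to 53791072) were hESC only, with no hNPC Pol II peak within 10 kb. The remaining pair of the 5 widest, on chromosome 6 (30581254 to 30584496, 3243 bp) and chromosome 5 (176921836 to 176925069, 3234 bp), overlapped hNPC Pol II peaks.

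The third comparison asked how often SOX2 and Pol II occupied the same place. Nearly all SOX2 peaks lay outside Pol II peaks, but the Pol II lists were much shorter than the SOX2 lists. They held 2491 against 17991 peaks in hESCs and 9322 against 67020 in hNPCs. This limits how many SOX2 peaks could overlap Pol II, so low shares do not show that SOX2 and Pol II sites were separate. In hESCs 373 of 17991 SOX2 peaks overlapped an hESC Pol II peak, or 2.07% (1.87 to 2.29%), and in hNPCs 3955 of 67020 overlapped an hNPC Pol II peak, or 5.90% (5.72 to 6.08%). Both shares exceeded chance, by 35.4-fold (31.9 to 39.1) in hESCs and 23.1-fold (22.4 to 23.9) in hNPCs, so the percentage was higher in hNPCs and the ratio to chance higher in hESCs. Chance overlap was 0.0586% in hESCs and 0.255% in hNPCs, and it rises with the length of the list overlapped. The ratios to chance in this comparison are therefore not directly comparable between the cell types. Over local displacement the ratios were 23.2-fold and 17.4-fold. With the hNPC Pol II list reduced to the hESC length, 1.64% of hNPC SOX2 peaks overlapped it when peaks were drawn at random. When the widest were taken it was 2.69%. A random draw lowers the share nearly in proportion to the list length by construction, and need not resemble a shallower library. Neither reduction settles the order between the cell types. With a reciprocal overlap of 50% the shares were 0.528% in hESCs and 1.74% in hNPCs. Seen from Pol II, 14.4% (13.02 to 15.8%) of hESC Pol II peaks overlapped an hESC SOX2 peak and 39.6% (38.6 to 40.6%) of hNPC Pol II peaks an hNPC SOX2 peak, which was 34.2-fold and 21.5-fold over chance.

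Shared SOX2 sites met Pol II more often than sites of a single cell type. In hESCs 3.56% (3.18 to 3.97%) of shared SOX2 peaks overlapped hESC Pol II, against 0.616% (0.466 to 0.800%) of hESC-only peaks. In hNPCs 11.4% (10.8 to 12.1%) of shared and 5.07% (4.89 to 5.25%) of hNPC-only peaks overlapped hNPC Pol II. When hNPC-only peaks were weighted to the widths of the shared peaks the share was 4.90% (resampling interval 4.72 to 5.11%), still under that of the shared peaks. The hESC-only SOX2 sites overlapped hNPC Pol II in 20 of 9086 cases, or 0.220% (0.135 to 0.340%), and hESC Pol II in 56 cases. Within 10 kb of an hNPC Pol II peak lay 5.11% (4.66 to 5.58%) of them, against 4.43% on average for shifted lists. The hNPC-only SOX2 sites overlapped hESC Pol II in 769 of 58252 cases, or 1.32% (1.23 to 1.42%). Leaving out every peak that overlaps the other cell type's SOX2 list also takes out overlaps with Pol II (the shared hESC peaks held 908 overlaps with hNPC Pol II), and the hNPC list, which sets the hESC-only class, is the longer one, so the single-cell-type shares are not compared with each other.

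The fourth comparison set changes in Pol II beside changes in SOX2. Pol II peaks present only in hESCs lay near hESC-only SOX2 peaks more often than other Pol II peaks did. Of the 609 hESC-only Pol II peaks 174 had an hESC-only SOX2 peak within 10 kb, or 28.6% (25.01 to 32.3%). The share was 8.66% (7.43 to 10.0%) for shared Pol II peaks in hESCs and 7.04% (6.48 to 7.64%) for hNPC-only Pol II peaks. For hESC SOX2 peaks of any class the gap was smaller, with 48.9% (44.9 to 53.0%), 40.5% (38.3 to 42.8%) and 33.0% (31.96 to 34.1%), and for shared SOX2 peaks, as listed in hNPCs, the share was 30.0% (26.4 to 33.9%) for hESC-only and 36.3% (34.1 to 38.5%) for shared Pol II peaks. Both hESC-only classes leave out peaks that overlap an hNPC list. An hNPC SOX2 peak of any class lay within 10 kb of 82.3% of shared Pol II peaks in hESCs and 65.2% of hESC-only ones. An hESC SOX2 peak near a shared Pol II peak may thus be classed as shared more often. How far this widened the gap was not tested. Local displacement of the Pol II peaks, for hESC-only SOX2 peaks, gave 8.67% on average and 11.3% at most for the hESC-only class, and 6.38% on average and 7.31% at most for the hNPC-only class. With Pol II peaks within 10 kb of each other joined into loci, the shares were 25.4% (21.2 to 30.1%) of 389 hESC-only loci, 8.38% (7.03 to 9.90%) of 1503 shared loci and 6.48% (5.78 to 7.24%) of 4537 hNPC-only loci.

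For hNPC-only SOX2 peaks the order was different. They lay within 10 kb of 67.3% (66.2 to 68.4%) of hNPC-only Pol II peaks and of 54.8% (50.8 to 58.8%) of hESC-only Pol II peaks, and the share was highest, 72.3% (70.2 to 74.3%), for the shared Pol II peaks of hESCs. All 3 shares exceeded local displacement, whose highest values were 34.6%, 35.1% and 35.9%. Joined into loci, the shares were 57.5% (56.1 to 58.9%) for hNPC-only, 49.6% (44.5 to 54.7%) for hESC-only and 69.4% (67.0 to 71.7%) for shared hESC loci.

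**Figure D5:**
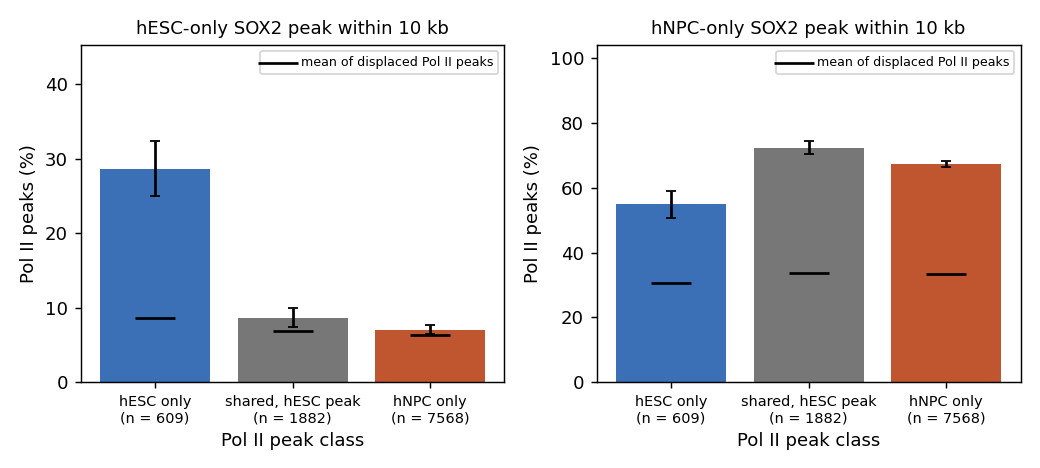
Percent of Pol II peaks (y axes) with an hESC-only (left) or hNPC-only (right) SOX2 peak within 10 kb, by Pol II class (x axes), with exact 95% binomial intervals and a black line at the mean of locally displaced Pol II peaks. The hESC-only Pol II peaks stand at 28.6% on the left, above the 8.66% and 7.04% of the other classes.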

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

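Chromosome M was outside the comparisons. The hNPC Pol II list held 5 peaks there, more than the 3 that a count of 0 allows, and the other 3 lists held 1 each. As a share of its list this was 0.0536% (0.0174 to 0.125%), against 0.0401% (0.00102 to 0.223%) for hESC Pol II, so no difference between the cell types was detectable. No explanation was tested.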

How the results depend on the processing

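Alternatives that use peak width, random thinning, removal of empty stretches, other distances or a Pol II list of reduced length were chosen after seeing the data. The other alternatives had been fixed before. Of 106 recomputed values 34 stayed within the main value's 95% interval, 72 moved outside it and 0 folds changed sides of 1. All 54 recomputed folds over chance, for 6 overlaps, lay above 1, the lowest at 17.4. The cause of a move was not tested unless the setting itself gives it, as a stricter rule or a shorter list does. Alternatives by the authors' score and all those on start sites, gene lists and motifs were not run. No paired analysis was possible because each condition had 1 library per antibody, and for the same reason no replicate was left out. Unknown depth limits every comparison of list lengths.

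In each list that follows, shared percentages and folds are for hESC SOX2, hNPC SOX2, hESC Pol II and hNPC Pol II peaks, and Pol II overlaps are for SOX2 peaks of hESCs and hNPCs. A reciprocal overlap of 50% gave 31.6, 8.48, 41.0 and 10.95% shared, folds of 87.6, 85.4, 514 and 504, Pol II overlaps of 0.528 and 1.74%, and for hNPCs a fold of 29.2. Centres within 500 bp gave 13.8% for hNPC SOX2 and 70.9% for hESC Pol II, folds of 22.8, 22.5, 192 and 193, and Pol II overlaps of 2.58 and 6.24% with folds of 30.3 and 20.8. Displacement by 5 to 200 kb gave folds of 28.2, 27.8, 63.3 and 63.3 for sharing and 23.2 and 17.4 for Pol II overlap. With empty stretches removed the folds were 34.6, 34.1, 214 and 199, and 21.9 for Pol II overlap in hNPCs. Uniform placement moved the hESC Pol II fold to 240.2.

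The wider 50% of each list gave 40.7% for hESC and 10.8% for hNPC SOX2, folds of 44.8, 43.8, 312 and 309, and Pol II overlaps of 1.62 and 4.22%, with a fold of 43.1 for hESCs. For each SOX2 class of the full lists, its own wider 50% was set against the wider 50% of the Pol II list. Overlap with Pol II of the same cell type was then 2.31% for shared hESC, 9.92% for shared hNPC and 3.08% for hNPC-only peaks. With the longer list of each pair reduced to its widest peaks, the shares were 21.8, 20.9, 47.5 and 40.8%, with folds of 40.4, 39.6, 360 and 310.2. The SOX2 list was then the reduced one for Pol II overlap, with 3.01 and 6.70% and folds of 41.9 and 19.1. Random thinning of the longer list gave 13.3% for hESC SOX2 and 20.6% for hESC Pol II, the latter with a fold of 201. Reducing only the hNPC Pol II list to the hESC length lowered the hNPC Pol II overlap to 1.64% at random and 2.69% by width. The random value nearly follows from the list length by construction, so its place below the 2.07% of hESCs shows no order between the cell types.

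A Pol II peak within 10 kb was found for 7.94% of shared hESC, 2.87% of hESC-only, 18.9% of shared hNPC and 12.0% of hNPC-only SOX2 peaks, in the same order as for overlap within each cell type. An hESC-only SOX2 peak overlapped 7.55% of hESC-only, 0.584% of shared hESC and 0.106% of hNPC-only Pol II peaks, and lay within 50 kb of 54.0, 30.6 and 27.5% of them.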

Other observations

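The groups and windows that follow, and the test on the widest 10% of peaks, were chosen after their values had been seen, and the test on joined Pol II loci was chosen after the same pattern had been seen for single peaks. Groups of 5 or more neighbouring SOX2 peaks were more frequent than under uniform placement in both cell types. With peaks within 10 kb of each other joined, hESCs held 27 groups of 5 or more SOX2 peaks, the largest of 7, and hNPCs held 1376 such groups, the largest of 30. Uniform placement of the same peaks gave 0.295 such groups on average for hESCs and 114 for hNPCs. It ignores regional density of peaks, and no local displacement was run for groups. These groups held 13.2% of hNPC and 0.828% of hESC SOX2 peaks. Sites listed for both antibodies in both cell types comprised 262 hESC SOX2 peaks, or 1.46%, that overlapped a peak in each of the other 3 lists. They were most of the 373 hESC SOX2 peaks that overlapped an hESC Pol II peak at all.

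Dense Pol II windows were partly common to the cell types. The 3 densest hESC windows lay on chromosome 6, from 26200001 to 26300000 with 18 hESC and 12 hNPC Pol II peaks, from 26100001 to 26200000 with 14 and 12, and from 27700001 to 27800000 with 14 and 8. A window on chromosome 6 from 94500001 to 94600000 held 12 hESC and 0 hNPC Pol II peaks, and one on chromosome 11 from 57400001 to 57500000 held 12 and 14. In hNPCs, 19 Pol II peaks lay on chromosome 5 from 92900001 to 93000000, on chromosome 6 from 99200001 to 99300000, on chromosome 13 from 100600001 to 100700000 and on chromosome 19 from 59000001 to 59100000, where hESCs had 0, 0, 5 and 4, and 18 lay on chromosome 7 from 99600001 to 99700000, where hESCs had 5. hESC Pol II peaks overlapped hNPC SOX2 peaks in 42.2% (40.3 to 44.2%) of cases, 24.5-fold over chance, and hESC SOX2 peaks in 14.4%, 34.2-fold over chance, with an hNPC SOX2 list 3.73 times as long.

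In all, 6 explanations were tested. The first pattern is the 9086 hESC SOX2 peaks without an hNPC peak. Whether the hNPC list is only a more sensitive one that contains the stronger hESC sites stays open. The shared percentage rose from 40.1% among the narrowest 10% of hESC peaks to 63.7% (61.4 to 65.9%) among the widest 10%, and the level of 90% set as a bound for the latter was an assumption made after that value had been seen, so it decides nothing. Randomly placed false-positive peaks in the hESC list would have neighbours no more often than displaced ones, but 11.5% of hESC-only peaks had another 1 to 10 kb away, against 7.25% on average and 8.23% at most in 200 displacements. This speaks against random placement of all of them, not of a part, and occupancy that differs between hESCs and hNPCs remains a hypothesis that 1 library per condition cannot test.

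The second pattern is that hESC SOX2 peaks overlapped hNPC SOX2 peaks far more often than shifted lists. Regional density of peaks would leave little excess over local displacement, yet the share was still 28.2-fold (27.8 to 28.6) over it. Regions recovered with any antibody may add to the overlap of any pair of lists, and this stays open. Among the 16517 hESC SOX2 peaks over 1 kb from every Pol II peak 45.9% (45.2 to 46.7%) were shared, but only 1474 peaks were left out, so that at least 44.99% had to remain and the test decides nothing. Regions that the input libraries would mark were not examined.

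The third pattern is that hESC-only Pol II peaks lay near hESC-only SOX2 peaks. If neighbouring Pol II peaks counted repeatedly produced it, joined loci would show no difference, but 25.4% (21.2 to 30.1%) of hESC-only loci had such a SOX2 peak, above 10.6%, the highest upper bound among the other classes of loci. The neighbourhoods were not free of SOX2 in hNPCs, since 65.2% (61.3 to 69.0%) of hESC-only Pol II peaks had some hNPC SOX2 peak within 10 kb, against at most 39.4% under displacement. No biological explanation was tested, both classes are defined by absence from the hNPC lists, and a difference in background between the hESC and hNPC preparations that acted on both antibodies remains open. Peak width as the source of the higher Pol II overlap of shared hNPC SOX2 peaks was also tested: weighted to the same widths, 4.90% of hNPC-only peaks overlapped, below the lower bound of 10.8% for shared peaks.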
